A study of Strongylocentrotus purpuratus with 24 samples.

How the data were processed

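Gene expression was measured in larvae of the purple sea urchin Strongylocentrotus purpuratus with 2-colour oligonucleotide microarrays. Fertilized eggs had been raised in seawater at 3 CO2 levels, 400, 800 and 1200 µatm, with 4 replicate cultures per level, and sampled as gastrulae and as plutei. Each of the 24 samples was RNA from about 60000 pooled larvae of 1 culture. Replicates of a group were therefore separate cultures, per the labels.

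Per the labels' protocols, 200 ng of total RNA was amplified and labelled, with Cy5 for the sample and Cy3 for a reference pooled from all samples. No dye was swapped, so dye bias of a probe is part of every ratio and cancels only in differences between groups. The deposited spot intensity values are mean pixel brightness in each channel and the median brightness of the local background, with no correction applied. They were extracted with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited scanner log10 ratio of Cy5 over Cy3 had been detrended for background and dye-normalized (linear and lowess) by that software, per the file headers. A further table of the authors holds a single log2 ratio per sample for 187 genes, chosen by a rule not given in the sources used here. All 187 genes in it equalled, within 0.001 in all 24 samples, the mean scanner log ratio (converted to base 2) over some of the gene's probes. All of a gene's probes were used for 43 of them. That match settled its base, its direction (Cy5 over Cy3) and that it was not centred. Column medians in that table ran from -0.51 (400 µatm gastrulae, replicate 1) to 0.14 (800 µatm gastrulae, replicate 4).

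Each array held 105072 spots, of which 103747 were probe spots and 1325 were controls. The 103612 probes stood for 28819 gene identifiers with the prefix SPU, with 2 to 4 probes per gene. The files do not pair these identifiers with gene names, and 0 of the 28819 matched the reference gene table supplied (assembly Spur_5.0). The 25 gene lists fixed beforehand (biomineralization, ion transport, chaperones and others) could not be matched to identifiers, so no list was tested.

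Intensities were background-corrected with limma's normexp method at an offset of 50 and normalized within each array by loess (span 0.3), with control and outlier-flagged spots at weight 0. This offset shrinks the fold changes of dim genes. Control spots and 923 outlier-flagged probe values were left out, and the 10 spots of each of 15 repeated probes were averaged. A gene was represented by its probe of highest mean signal. It was tested if that probe was well above background in Cy5 on at least 4 arrays, which kept 12494 genes and left out 16325.

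Files were compared in pairs before averaging, in the reference channel, where all arrays carried the same RNA. In the 800 µatm gastrula group, files 1 and 2 and files 3 and 4 shared 100% of their saturated Cy3 spots (116 and 124 spots), against at most 90.9% in the other pairs. Their deviations from the mean Cy3 signal correlated at 0.927 and 0.952 over 4617 spots, against at most 0.746 in the other pairs of the 276. That includes 10 pairs from shared slides. All arrays carried the same reference RNA, so the sample does not account for such deviations. Different arrays shared them in part. In plutei they correlated between 0.0412 and 0.626 for arrays at 400 and 1200 µatm, and between -0.553 and 0.110 for arrays at 400 and 800 µatm. How such differences in the reference channel bear on the CO2 comparisons was not tested. Because the 2 pairs stood apart from all others in both measures, each was taken as 2 readings of 1 array, averaged and counted once. The analysis then held 22 separate arrays in place of the 24 planned: 2 for 800 µatm gastrulae and 4 for each other group.

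The log2 ratios were fitted in 1 model of 6 group means with limma's lmFit and eBayes, so that all groups shared an estimate of the spread between cultures. Each CO2 pair within a stage, any CO2 difference within a stage (moderated F test), the stage by CO2 interaction (moderated F test) and plutei against gastrulae (mean of the 3 levels) were tested with Benjamini-Hochberg adjustment at 5%. The tests, the filter, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The naming rule took the genes of largest change that carry an informative name, and none of the identifiers did. The 4 identifiers printed are instead the 2 largest called differences in each direction between stages among genes above background on all 22 arrays, unsaturated and without missing values. This selection was made after the values were seen.

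Pairing was checked through the correlation of deviations from group means. At 400 and 1200 µatm, all 8 pairs of gastrula and pluteus arrays with the same CO2 level and replicate number correlated above 0.1 (0.308 to 0.522), and each gastrula array correlated best with the pluteus array of its own number. The pairing thus comes from the labels' replicate numbers and these correlations. Arrays of the 2 stages are therefore not independent, and the main fit did not pair them. The culture was used as a block in an alternative, at 400 and 1200 µatm alone. At 800 µatm the gastrula arrays carry no single number.

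Slides and scan days each held arrays of 1 group, and 5 groups spanned several days, so both were tested as random blocks with duplicateCorrelation. The 800 µatm gastrula arrays were all scanned on 1 day of their own, so for that group scan day and group cannot be told apart. Alternatives covered background correction, normalization, the filter, the probe rule, the samples in the fit, replicate and slide blocks, the authors' value table and leaving out each array. The fit planned beforehand took all 24 files as separate replicates. It was made an alternative, and a block for 4 sets of arrays found in the data was added, after the data were seen. The clustering behind the sets was rerun without the 187 genes of the authors' table after a first run had included them.

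The fits were tested on simulated data with 200 changed genes among 12494, drawn with the real gene-wise spread. For plutei at 1200 against 400 µatm, 34.5% of genes changed by 1.5-fold were recovered, 93.0% at 2-fold and 100% at 4-fold. For gastrulae at 800 against 400 µatm, with only 2 arrays in a group, recovery was 7.0%, 74.5% and 97.5%. For the interaction it was 0, 63.5% and 97.5%. The draws used the gene-wise spread. Recovery under the deviations that sets of arrays share, described below, was not tested. The number of arrays limits the precision of each value. R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and, for the figures, matplotlib 3.10.9 were used.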

Results

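Gene expression was profiled in sea urchin gastrulae, embryos in which the gut is forming, and in plutei, the swimming larvae that carry a calcium carbonate skeleton. Cultures were held at 400, 800 or 1200 µatm seawater CO2, which lowers pH as it rises. The series addressed how larvae respond to elevated CO2. Between 12.5% and 38.5% of probe spots per array were well above background in the sample channel (median 21.9%), and between 17.7% and 27.7% in the reference channel. Of the 12494 genes tested, 3628 were above background on all 22 arrays. The median standard deviation of a gene's log2 ratio between cultures of a group lay between 0.16 (800 µatm gastrulae, n = 2) and 0.22 (400 µatm gastrulae, n = 4). Log ratios of gastrula and pluteus files, taken over all probes, correlated between -0.219 and 0.136. Files of 1 stage correlated between 0.142 and 0.739. Both 800 µatm gastrula arrays had been deposited as a pair of readings each and were counted once, as the plot of file pairs shows.

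**Figure D1:**
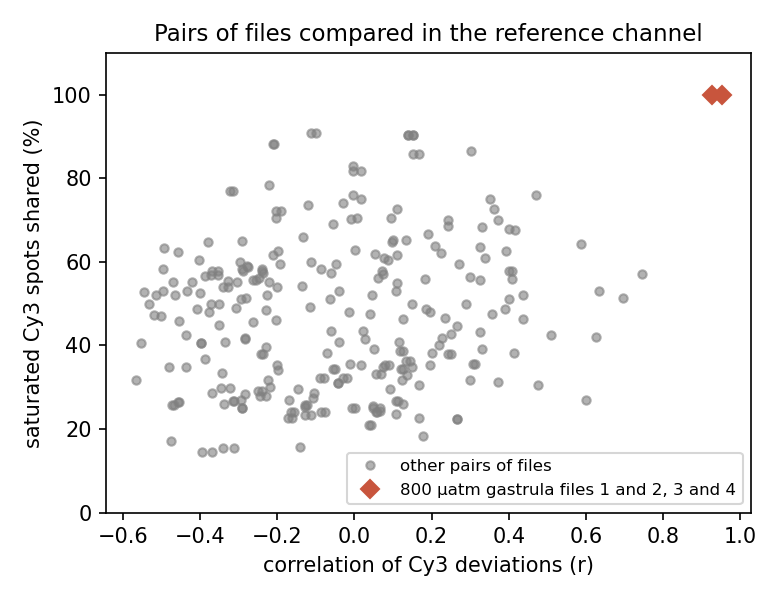
Each point is a pair of the 24 files. The x axis gives the correlation of deviations from the mean log2 Cy3 signal, and the y axis the percent of saturated Cy3 spots the files share. The 2 red diamonds, 800 µatm gastrula files 1 with 2 and 3 with 4, sit at correlations of 0.927 and 0.952 and at 100%, apart from all other pairs.

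Development from gastrula to pluteus changed a large part of the measured transcriptome. Of 12494 genes, 3154 were higher and 2780 lower in plutei than in gastrulae, averaged over the 3 CO2 levels (limma, adjusted p under 0.05). Which direction held more genes depended on the setting: 3032 were higher and 3154 lower with the scanner log ratio, 2118 and 2148 with median centring, and 877 and 1127 among genes above background on all arrays. Among the genes called 682 were higher by over 2-fold and 266 lower by over 2-fold. Over 4-fold, 215 were higher and 29 lower. The median difference was 0.55 on the log2 scale for genes higher in plutei and -0.44 for genes lower in plutei. In terms of detection, 135 genes were well above background on all 12 pluteus arrays and on no gastrula array, and 4 genes showed the reverse. Signal below background does not show that a transcript was absent, and these counts also depend on array brightness, which ran from 12.5% to 30.2% of probe spots above background in gastrula files and from 14.8% to 38.5% in pluteus files. For 1661 of the 12334 tested genes with a value on every array (13.5%), the 12 pluteus arrays did not overlap the 10 gastrula arrays, where chance leaves 0.00031% of genes without overlap. All 1661 were among the called genes.

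Among genes above background and unsaturated on all 22 arrays, the largest called increases were in SPU_025072 and SPU_025092. Genes below background on some arrays reached a log2 difference of 6.35. SPU_025072 averaged -4.06 ± 0.28 in gastrulae (log2 ratio to the reference, SD, n = 10) and 0.42 ± 0.41 in plutei (SD, n = 12). Its log2 difference was 4.49 (SE 0.15, limma adjusted p = 2.13e-17). SPU_025092 rose from -4.09 ± 0.46 to 0.27 ± 0.20, a log2 difference of 4.38 (SE 0.12, limma adjusted p = 4.96e-19). Under the same limit the largest called decreases were in SPU_006187, from 1.37 ± 0.31 in gastrulae to -2.66 ± 0.23 in plutei, and SPU_023890, from 1.50 ± 0.39 to -1.97 ± 0.24. Their log2 differences were -4.02 (SE 0.12) and -3.45 (SE 0.14), with limma adjusted p of 3.28e-18 and 1.00e-15. All 4 probes of each of these 4 genes moved in the same direction. What these identifiers encode is not given in the files.

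**Figure D2:**
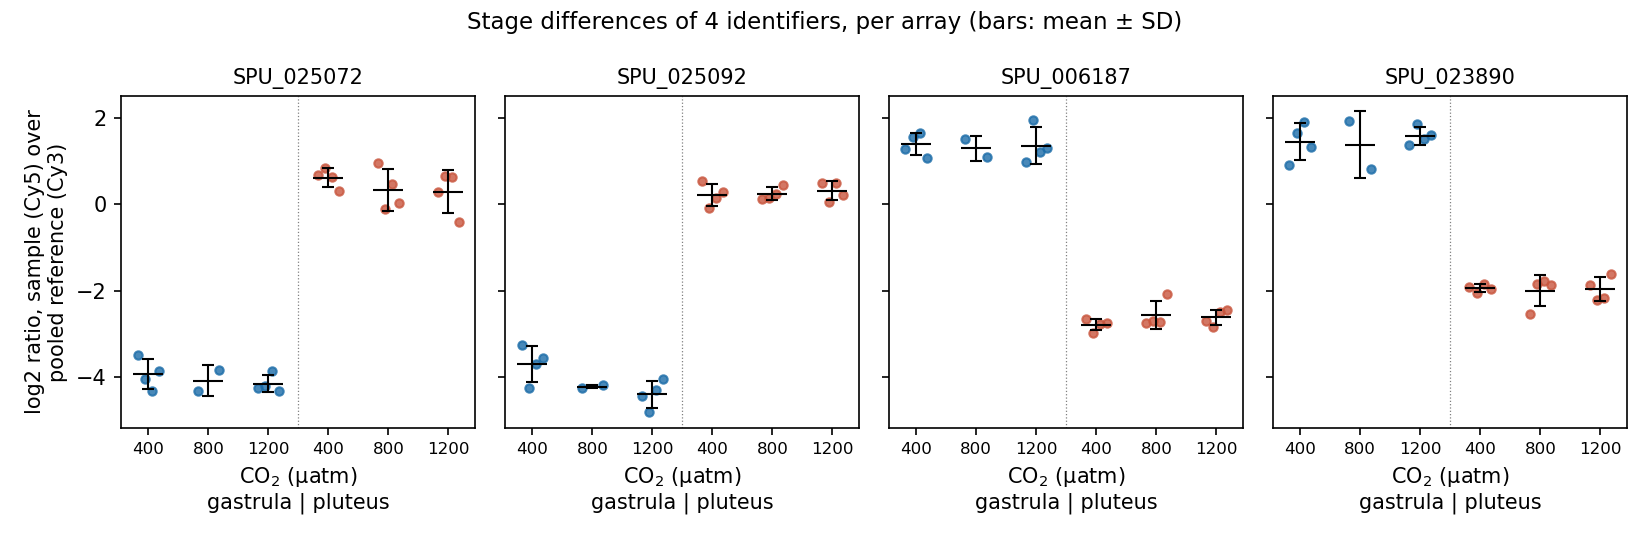
Log2 ratio of sample over pooled reference (y axis) in each of the 22 arrays, by CO2 level (x axis), for the 4 identifiers with the 2 largest called stage differences in each direction among genes above background and unsaturated on all arrays. Points are arrays (blue gastrulae, red plutei) and bars are the mean ± SD of each group. Within each panel the 2 stages are far apart at each CO2 level, with stage differences between -4.02 and 4.49.

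The stage difference was shared by the CO2 levels. Of the genes higher in plutei, 3115 of 3154 differed in that direction at each of the 3 levels, and 2734 of the 2780 lower genes were lower at each. Both lists were called on the mean of the 3 level differences. Such agreement in sign therefore largely follows from the selection and is not separate evidence. Across genes, which are not independent replicates, the stage differences at 400 and 800 µatm correlated at 0.912. Those at 400 and 1200 µatm correlated at 0.950, and those at 800 and 1200 µatm at 0.931. The number of called genes was 5934 in all, and a fit of the 3628 genes above background on all arrays called 2004, which included all 1977 of them called among the 12494.

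In gastrulae, no gene was called between CO2 levels. At 800 against 400 µatm (n = 2 and 4), limma called 0 of 12494 genes, with 789 (6.32%) at an unadjusted p under 0.05. The gene of lowest p differed by 0.83 on the log2 scale (SE 0.16, limma adjusted p = 0.40). At 1200 against 400 µatm, limma called 0 genes, with 503 (4.03%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.998. At 1200 against 800 µatm, limma called 0 genes, with 457 (3.66%) at an unadjusted p under 0.05 and a lowest adjusted p of 1.00. The test for any CO2 difference called 0 genes, with 534 at an unadjusted p under 0.05. These unadjusted counts depend on single arrays. At 800 against 400 µatm the count was 1096 without 400 µatm replicate 3 and 641 without 400 µatm replicate 1. At 1200 against 400 µatm it was 823 without 400 µatm replicate 3 and 332 without 1200 µatm replicate 1, and for any CO2 difference 812 without 400 µatm replicate 3. Median absolute differences were 0.15, 0.11 and 0.13 on the log2 scale for these 3 pairs, against 0.23 between stages. Such medians include the error of the estimates, which was larger for these pairs (median SE 0.196, 0.160 and 0.196) than between stages (0.0996). They are therefore not taken as sizes of CO2 effects. The 95% confidence interval of the difference lay within 2-fold for 93.8%, 98.3% and 95.3% of the genes, on a scale that compresses dim genes. The 800 µatm group decides part of this: without its array from files 1 and 2 limma called 8 genes against 400 µatm, and without that from files 3 and 4 it called 1, with a single array left that is assumed to vary like the others. Without files 3 and 4, 1 gene was also called at 1200 against 800 µatm and for any CO2 difference.

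In plutei, as in gastrulae, no gene was called between CO2 levels. At 800 against 400 µatm (n = 4 and 4), limma called 0 of 12494 genes, with 200 (1.60%) at an unadjusted p under 0.05. At 1200 against 400 µatm it called 0, with 0.984% of the genes, and at 1200 against 800 µatm 0, with 108 (0.864%), at that unadjusted level. The test for any CO2 difference called 0 genes, with 90 at an unadjusted p under 0.05. Without replicate 2 at 1200 µatm, the unadjusted counts were 244 at 1200 against 400 µatm, 290 at 1200 against 800 µatm and 167 for any CO2 difference, and without replicate 4 at 800 µatm 195 genes reached that level at 1200 against 800 µatm. With all arrays, the pairwise shares lay below what chance alone gives at a p under 0.05. Each pluteus group held 1 array of each of the 4 sets described below, so differences between sets stay in the error of this fit. With the sets as a block the shares were 3.33%, 2.52% and 2.17% for the same pairs, still below chance. The low shares are therefore not taken as evidence that CO2 effects are small. Median absolute differences without the block were 0.09, 0.09 and 0.08 on the log2 scale, below the median SE of 0.160 of each pair. The pair with equal numbers in both stages, 1200 against 400 µatm, had 0.11 in gastrulae and 0.09 in plutei, a contrast that was not tested, while the gastrula pairs with 800 µatm had larger errors (median SE 0.196 against 0.160). In plutei the 95% confidence interval lay within 2-fold for 99.0%, 98.8% and 98.9% of the genes. No alternative gave a called gene in plutei. In genes that rise from gastrula to pluteus, 1253 of 3154 were higher at 1200 than at 400 µatm, with a median of -0.03 on the log2 scale. In genes that fall over that step 1747 of 2780 were higher, with a median of 0.04. Among genes with no called stage difference 3563 of 6560 were higher, with a median of 0.01. This lean rested on 1 array: without replicate 4 at 1200 µatm, 1565 of 3154 and 1441 of 2780 genes were higher, with medians of 0.00 and 0.01. In gastrulae at the same levels both stage lists leaned lower, with 1361 of 3154 and 1261 of 2780 genes higher at 1200 µatm. In plutei neither list held a gene past the threshold (0 adjusted over all genes), with 30 and 39 members at an unadjusted p under 0.05.

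**Figure D3:**
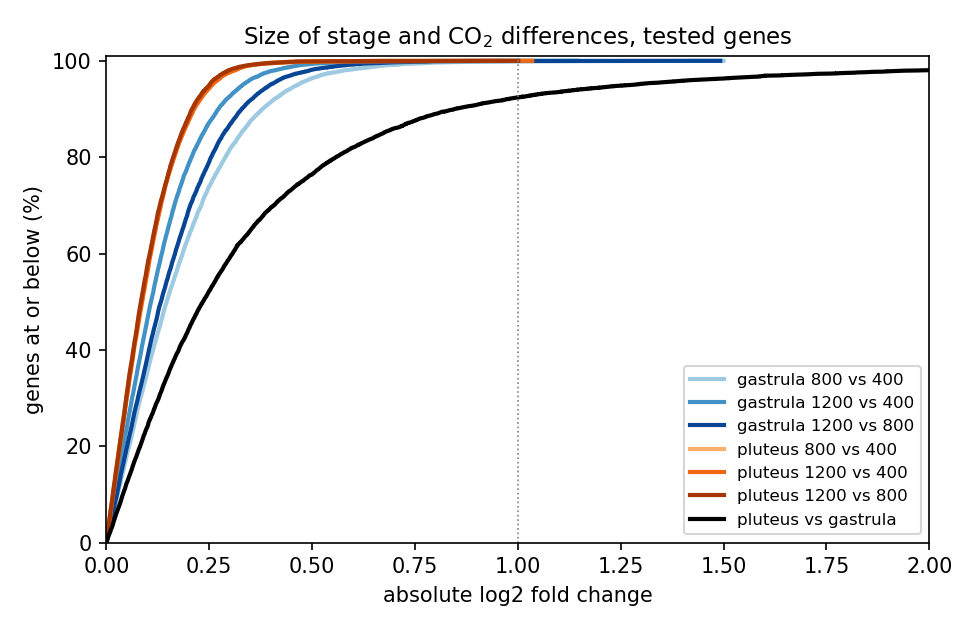
Cumulative percent of the 12494 tested genes (y axis) against the absolute log2 fold change (x axis), for the 6 pairwise CO2 comparisons and for plutei against gastrulae. The dotted line marks 2-fold. The CO2 curves (medians 0.08 to 0.15) rise left of the stage curve (median 0.23). All curves include the error of the estimates, which is larger for the CO2 pairs (median SE 0.160 to 0.196) than between stages (0.0996). The CO2 medians are therefore not sizes of CO2 effects. Of the 3 gastrula curves (blue), 2 involve the 800 µatm group of 2 arrays, whose differences carry the larger errors.

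The stage by CO2 interaction asked whether CO2 differences themselves differed between gastrulae and plutei. It called 0 of 12494 genes by limma's F test, with 255 (2.04%) at an unadjusted p under 0.05, and 1 gene without the 800 µatm gastrula array from files 3 and 4. The unadjusted count was 388 without 400 µatm gastrula replicate 3 and 401 without the 800 µatm gastrula array from files 1 and 2. It was 510 (4.08%) with the culture as a replicate block at 400 and 1200 µatm alone and 651 (5.21%) with the 4 sets described below as a block, again with 0 called genes. A CO2 response of 1 stage alone was thus not shown for any gene in the full set of arrays.

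The authors' deposited table lists 187 genes, all of them among those tested. In gastrulae at 800 against 400 µatm, 64 of the 187 were lower and the others higher, with a median log2 difference of 0.49, and 93 (49.7%) had an unadjusted p under 0.05. Adjusted over the list alone, 18 passed, and 0 passed over all genes (limma). At 1200 against 400 µatm, 25 of the 187 had an unadjusted p under 0.05, with a median of 0.11, and 0 passed adjusted over the list alone. In plutei 1 of the 187 reached that unadjusted level at 800 against 400 µatm, 1 at 1200 against 400 µatm and 0 at 1200 against 800 µatm. How the list was chosen is not given in the sources used here, so its counts are not taken as independent evidence of a direction. Of the 187, 49 were higher and 30 lower in plutei than in gastrulae. With the 24 files entered as separate replicates, 130 of the 187 had an unadjusted p under 0.05 at 800 against 400 µatm in gastrulae and 111 passed adjusted over the list alone. With the 4 sets of arrays described below as a block, 125 had an unadjusted p under 0.05, 94 passed adjusted over the list alone and 0 passed over all genes. In 1 set with 800 µatm gastrulae, the mean shift in the direction of the 800 minus 400 µatm difference was 0.958. In the other such set it was 0.176. Each of these values compares 1 array at 800 µatm with 1 array at 400 µatm. The direction was taken from a difference that includes these arrays, so a positive shift is partly built in.

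Cultures differed from each other in ways that CO2 and stage do not account for. Deviations from the stage mean were clustered on 6073 genes, and the arrays fell into 4 sets, with 1 array of each group in each set, except that the 800 µatm gastrulae stood in only 2 sets. In 6261 held-out genes, arrays of 1 set correlated at a mean of 0.367 and arrays of different sets at -0.162. The gastrula and pluteus arrays of the same culture stood in the same set in all 8 cultures at 400 and 1200 µatm. These sets were defined from the data and are not groups of the study. With the set as a block, limma still called 0 genes in all 9 CO2 results, with 1296 genes (10.4%) at an unadjusted p under 0.05 for gastrulae at 800 against 400 µatm, 998 (7.99%) at 1200 against 400 µatm, and 416 (3.33%) and 315 (2.52%) for the same pairs in plutei. The lowest limma adjusted p with this block was 0.137 for gastrulae at 800 against 400 µatm, 0.0833 at 1200 against 400 µatm and 0.0959 at 1200 against 800 µatm. The sets were clustered on part of the genes tested here, so p-values with this block may be too small. Without the block, differences between the sets stay in the error, which can lower the unadjusted shares.

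**Figure D4:**
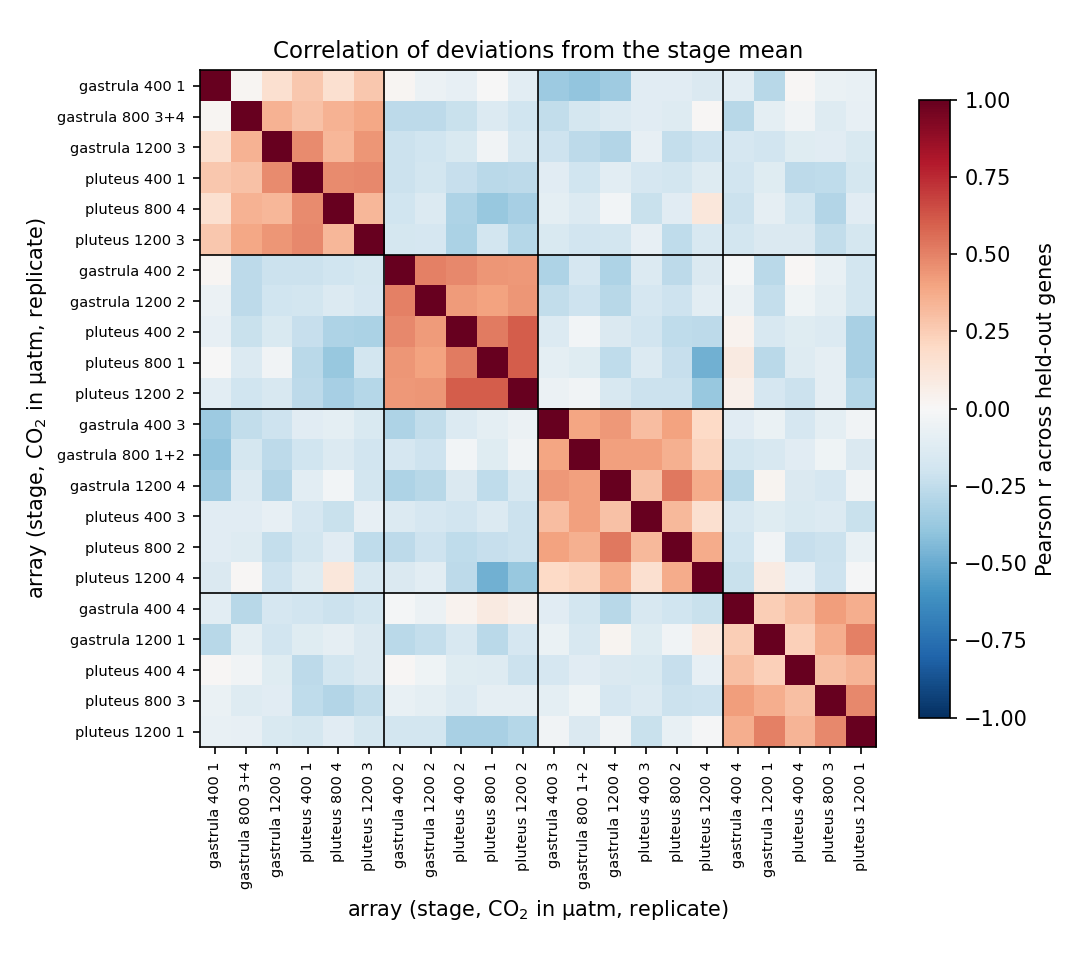
Pearson correlation (colour, -1 to 1) across 6261 held-out genes between the 22 arrays (both axes, by stage, CO2 level and replicate) of their deviations from the stage mean. Black lines part the 4 sets. Red blocks along the diagonal show that arrays of 1 set, from both stages and from different CO2 levels, resemble each other (mean 0.367, lowest 0.0201) more than arrays of different sets do (mean -0.162, highest 0.113), with an overlap of single pairs.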

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

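The search for outlying arrays was planned. The tests on the sets of arrays for slide or scan day and for a shared origin, the test of hidden changes with the set block, and the test of differences that share no array were chosen after the results were seen.

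Among 32 groups of 4 arrays, 2 held an array far from the other 3, where chance alone gives about 5% of groups. For SPU_006187, the pluteus array at 800 µatm with replicate number 4 had a log2 ratio of -2.09, while the other 3 lay between -2.75 and -2.72. For SPU_023890, the pluteus array at 800 µatm with replicate number 1 had a log2 ratio of -2.54, while the other 3 lay between -1.86 and -1.77. Both stayed far from the gastrula means of 1.37 and 1.50.

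The first pattern is the 4 sets of arrays that cut across CO2 levels and stages. In held-out genes the mean correlation was higher by 0.529 within sets than between them (permutation test, p = 1e-04, the smallest that 10000 permutations give), which argues against noise of the clustered genes, and the share of probes above background did not separate the sets (permutation p = 0.659, 0.0841 of its variance between sets). Slide or scan day is argued against by 0 of 10 pairs of arrays from a slide falling in the same set, and sequence variants under single probes by a correlation of 0.780 or more between set differences of a gene's brightest and second probe across 9692 genes (0.965 for the stage difference). All 8 cultures read at both stages kept their set, a result consistent with the hypothesis that cultures of one set share an origin the labels do not name, such as their parents. Parentage was not given in the sources used here, so this stays open.

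The second pattern is the lack of called genes between CO2 levels. Slower development under higher CO2 was measured by a score that places each array between the gastrula (0) and pluteus (1) mean of the 800 µatm arrays, but a delay would add differences between levels, so it does not account for their lack whatever the score. Plutei at 1200 µatm scored 0.958 ± 0.105 (SD, n = 4) and at 400 µatm 1.00 ± 0.03 (SD, n = 4), a difference of -0.0431 (SE 0.0541, exact permutation test, two-sided p = 0.571, smallest possible 0.0286) that was 0.00507 without 1200 µatm replicate 4. The idea that differences between cultures hide changes in single genes met 0 called genes in each pairwise comparison with the sets as a block, but unadjusted shares rose to at most 10.4% and the lowest limma adjusted p fell to 0.0833 (gastrulae at 1200 against 400 µatm), so this argues only against many genes past the threshold being hidden. Changes below 2-fold may still be missed, since simulated 1.5-fold changes in plutei at 1200 against 400 µatm were recovered in 34.5% of genes. That rate was not tested under the deviations that sets of arrays share.

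The third pattern is the difference of the authors' 187 genes in gastrulae at 800 µatm. Their 800 minus 400 µatm difference correlated across genes at 0.744 with a difference between sets (0.367 over all tested genes). The latter compared the 2 sets that hold the 800 µatm gastrulae with the other 2, in plutei and 1200 µatm gastrulae. Part of the 800 minus 400 µatm difference may thus come from which cultures were read. With the set block its median absolute value was 0.49, against 0.60 without. The mean shift in its direction was 0.958 within 1 of the 2 sets with 800 µatm gastrulae and 0.176 within the other. Each value compares 1 array at 800 µatm with 1 array at 400 µatm, and the direction was taken from a difference that includes them. A positive shift is therefore partly built in. The larger value compares the array from files 3 and 4 with 400 µatm replicate 1. What remains with the block thus rests largely on this pair of arrays. Whether that reflects the set or a single array cannot be told. Counting 2 readings of an array as replicates raised the genes at an unadjusted p under 0.05 from 93 to 130, less than the 1.5-fold set beforehand, though those passing over the list alone went from 18 to 111. A CO2 response of gastrulae met the criterion set beforehand: with the set block 93.0% of the genes moved the same way at 1200 as at 800 µatm, with a mean shift 0.558 as large, but both differences use the same 400 µatm arrays, and a test without shared arrays was therefore put in its place after that result was seen. There the differences correlated at 0.539 across 184 of the genes and at 0.0949 over all genes. However, 15 of 100 relabellings within sets gave their own 187 lowest-p genes as high a value. The 187 lowest-p genes of the real labels gave 0.372, against a median of 0.330 over the relabellings. A CO2 response shared by 800 and 1200 µatm thus cannot be told apart from the choice of genes.

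The 800 µatm gastrula arrays were scanned on a day of their own, so scan day is confounded with this group.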

How the results depend on the processing

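The averaging of repeat readings, which made the planned fit of all 24 files an alternative, and the block for 4 sets of arrays were chosen after the data were seen. The other alternatives were planned. With all 24 files limma called 0 genes in all 9 CO2 results, with 1562 genes at an unadjusted p under 0.05 for gastrulae at 800 against 400 µatm, and 6391 stage genes. Of 247 alternative counts of called genes, 240 stayed within 1.5 times the value reported. All 9 CO2 results stayed at 0 called genes in 206 of 211 alternatives, and the 5 exceptions left out an 800 µatm gastrula array: counts ran from 0 to 8 for gastrulae at 800 against 400 µatm, and from 0 to 1 at 1200 against 800 µatm, for any CO2 difference and for the interaction. With 1 array left in that group, the cause was not tested further. The stage count moved to 2004 when signal above background was required on all arrays and to 74 in the authors' table, because only 3628 and 187 genes were then tested. Otherwise it lay between 4266 (median centring) and 6851 (set block), and between 5353 and 5948 on leaving out each array. All 141 alternative values of the 4 named identifiers kept their direction and stayed past the threshold. With the culture as a replicate block, over 16 arrays at 400 and 1200 µatm, 6260 stage genes were called, against 5290 without the block. Within a stage, replicate number 2 paired the arrays at 400 and 1200 µatm, with correlations of 0.504 in gastrulae and 0.661 in plutei. Other pairs of the same number across CO2 levels correlated between -0.273 and 0.156. The replicate block gave 0 calls in the 5 results it could be run for. It was not run where an 800 µatm gastrula array enters, since these have no single number. Random blocks for slide and scan day had correlations of 0.00849 and 0.00179 and gave 5912 and 5930 stage genes. Of the 10 pairs of arrays from a slide, 0 stood in the same set, and arrays of different sets correlated at a mean of -0.162. Differences between sets can thus lower these correlations, which do not show that slide or scan day matters little. With median centring the median log2 difference of all genes was -0.30 at 800 against 400 µatm in gastrulae, against -0.03 with loess, and -0.15 at 1200 against 400 µatm in plutei, against 0.01 with loess. Counts at an unadjusted p under 0.05 moved more than the calls did: with median centring 1558 genes reached it at 800 against 400 µatm in gastrulae, 172 at 1200 against 400 µatm in gastrulae and 54 at 800 against 400 µatm in plutei. The alternatives for gene list shifts were not run, since no list could be matched. Signal over background limits the tests: 16325 genes too dim for the filter were left out, and fold changes of dim genes are compressed.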

Other observations

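The splits of the samples were planned; the comparison of splits with sets was made after the result was seen.

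Gastrulae at 1200 µatm lay slightly lower on the score from gastrula to pluteus than those at 400 µatm, at 0.0400 ± 0.0195 against 0.0809 ± 0.0323 (SD, n = 4 each). The difference was -0.041 and was negative in all 4 sets, between -0.0968 and -0.0101, with an exact permutation two-sided p = 0.0571, or 0.229 after adjustment over 4 score comparisons. Without 400 µatm replicate 4 the difference was -0.0267. The SE of the difference was 0.0189, and the smallest p this design allows is 0.0286. For 800 against 400 µatm the score was instead placed between the gastrula and pluteus means of the 1200 µatm arrays. In gastrulae the difference was 0.00511 (exact permutation p = 0.867, n = 2 and 4) and ran from -0.0252 to 0.0354 on leaving out each array. In plutei it was -0.0228 (exact permutation p = 0.457, n = 4 and 4) and ran from -0.0493 to -0.00626.

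The stage result stood out from regrouped arrays: 1 of 100 splits of the samples, the real one, gave as many as 5934 called genes, and the highest other split gave 17. In the 4 pairwise CO2 comparisons with 4 arrays per level the real count was 0, so all 35 splits of the samples reach it whatever they call, and the count says nothing further about CO2. The comparisons with 800 µatm gastrulae, with 2 arrays, were not split. The highest other splits called 18 genes for gastrulae at 1200 against 400 µatm, 4 for plutei at 800 against 400 µatm, 0 at 1200 against 400 µatm and 10 at 1200 against 800 µatm. For any CO2 difference in plutei, the same holds for all 100 splits, and the highest other gave 6. The split with 18 genes and that with 4 kept each of the 4 sets whole on one side, while the split with 10 kept 2 of the 4 whole. In each comparison 3 splits keep all sets whole, and at most 1 of the 3 called any gene. Such a split leaves differences between the sets on the same side in the error. The splits therefore cannot weigh set effects against CO2 effects.

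In the authors' 187 genes in plutei, the 800 and 1200 µatm differences taken from separate pairs of sets correlated between -0.239 and 0.304 over 6 choices of sets. Gastrulae allow a single such choice, and the stages were not compared by a test.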
